A study of Arabidopsis thaliana with 12 samples.

How the data were processed

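Total RNA from leaves of 2-week-old Arabidopsis plants was labelled with biotin after one-cycle cDNA synthesis and in vitro transcription and hybridized to Affymetrix arrays with 22810 probe sets, of which 64 are control probe sets. The plants were the wild type Columbia-0 (Col-0) and er-105, a mutant allele of the receptor kinase gene ERECTA, grown at 21 °C and either left untreated or kept at 40 °C for 6 h. Each of the 4 groups has 3 arrays, numbered as biological replicates 1 to 3, and all 12 arrays were used. Per the labels, the authors processed the arrays with RMA in Partek, whose versions are not stated, and the deposited values are log2 intensities on a single channel, so a higher value means more RNA. RMA subtracts background, normalizes quantiles and summarizes the probes of a set, which compresses differences near the background. The array medians still ranged from 5.19 to 5.49, and which arrays were normalized together is not given in the sources used here. Differences between groups can therefore hold a part that comes from scaling. The values were used as deposited, and other scalings were tried as alternatives. The values lay between 2.71 and 14.1. No counts or depths exist for arrays, and the number of arrays limits the precision.

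Probe sets were given a gene only from the supplied list of probe sets and genes, joined to a gene table of assembly TAIR10.1 that served for locus codes, symbols and the order of neighbouring loci. The list gave a gene for 14016 probe sets, 503 of them with several genes, and 8730 had none. Of the 13513 probe sets with exactly 1 gene, 13436 were joined by Entrez ID and 77 by symbol. A gene with several such probe sets, which held for 147 genes, was represented by the set with the highest mean, and 13355 genes were tested. Because 8730 probe sets had no gene listed, many genes with a known role in heat or in leaf development, ERECTA among them, were not analysed here by name.

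A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without a trend), and 5 contrasts were tested: the heat response in each genotype, the genotype difference at 21 °C and after 40 °C, and their interaction, which is the heat response in er-105 minus that in Col-0. The Benjamini-Hochberg adjustment covered all genes within a contrast, and a gene was called past the threshold at an adjusted p under 0.05. Errors of log2 differences are standard errors (SE) of the model, and errors of group means are standard deviations (SD) over 3 arrays. All tests were two-sided.

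Gene lists were tested with limma's camera, which compares the members of a list with all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists of a contrast. Of 30 lists fixed in advance, with 521 members, 83 members were measured under a gene name, and the 8 lists with at least 4 measured members were tested. These were small heat shock proteins, larger chaperones with co-chaperones, folding in the endoplasmic reticulum, autophagy, photosystem and light-harvesting subunits, the Calvin cycle with photorespiration, the ERECTA pathway with stomatal development, and reference genes. A further 25 lists were added after the annotation and the first values had been seen: genes encoded in the plastid and the mitochondrion, and nuclear families by symbol. The lists of plastid photosystem subunits, ribosomal proteins, NAD(P)H dehydrogenase subunits and RNA polymerase subunits are parts of the list of plastid-encoded genes. Calls of these lists are therefore not separate results. Each list was also tested with a correlation estimated from the data, and with limma's fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes.

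The groups, the contrasts, the thresholds, the 30 lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took the 6 highest and the 6 lowest genes of a contrast among those past the threshold whose arrays did not overlap between the groups (for the interaction, among those past the threshold). It added 3 members past the threshold for each called list fixed in advance, and HSP17.6C and RCA always. Members of added lists, single genes per array and genes beyond the rule were chosen after their values were seen.

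Whether the replicate numbers pair the arrays was tested from the deviations of each array from its group mean across genes. At 21 °C the deviations of equal numbers of Col-0 and er-105 correlated at 0.84, 0.57 and 0.42, but those of replicates 2 and 3 also correlated across numbers at 0.52 and 0.67, and after 40 °C equal numbers gave 0.32, 0.04 and 0.22. Between the temperatures equal numbers correlated at −0.06, 0.00 and −0.10 in Col-0 and at −0.04, 0.00 and 0.01 in er-105. Every pair of equal numbers thus correlated above 0.1 at 21 °C only, and by that rule equal numbers were taken as paired there. Deviations cancel out within a group, so a deviation shared by the replicate 1 arrays alone makes replicates 2 and 3 correlate within and across numbers. A pairing by number is therefore not shown for replicates 2 and 3. The model, set beforehand, has no block, and values with the replicate number as a block are printed where it changes a call.

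Alternatives changed 1 choice at a time: each contrast on its own arrays, a trend and robust moderation, no moderation, array weights, the replicate block, centring on array medians, on 18 hybridization control sets or on 8 reference genes, quantile normalization again, genes under the 40th percentile of brightness left out, all 22746 probe sets other than controls, the mean of a gene's probe sets, a change of at least 2-fold, an adjusted p under 0.01, and each array left out in turn. Added after the data had been seen were fits without both replicate 1 arrays at 21 °C, with these as the only controls, with the array's 5′ minus 3′ signal over GAPDH, actin and ubiquitin control sets as a covariate, and with a block for each replicate number within a temperature. The model was tested on simulated data made from the means and spreads of the real genes, in which 200 genes were changed. For changes of 2-fold it recovered 67.2% in Col-0 and 74.6% in er-105 for heat, 77.6% for the genotype difference at 21 °C, 71.6% after 40 °C and 44.8% for the interaction, and between 2 and 11 of the unchanged genes were called. Noise was drawn independently for each array, with the same spread of a gene in all 4 groups. The shift shared by the replicate 1 arrays at 21 °C was thus not simulated, and these percentages need not hold for contrasts with those arrays. In a simulation with 1 changed list, camera called that list and also 2 of the 32 unchanged ones, so small list shifts can be called without a change.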

Results

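Transcript levels were measured in leaves of 2-week-old Arabidopsis plants of the wild type Columbia-0 (Col-0) and of er-105, a mutant allele of the receptor kinase gene ERECTA. Plants were untreated at 21 °C or had been at 40 °C for 6 h, with 3 arrays in each of the 4 groups. The values are log2 intensities from RMA as deposited, with array medians from 5.19 to 5.49, and 13355 genes had a named probe set. The design asks how leaves respond to heat, and whether that response and the levels before and after it depend on ERECTA.

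The arrays did not fall into the 4 groups alone. Across genes, which are not independent replicates, the replicate 1 arrays of both genotypes at 21 °C correlated at 0.993 with each other and at 0.946 to 0.963 with the other 4 arrays at 21 °C, which correlated at 0.986 to 0.993 among themselves. The 6 arrays after 40 °C correlated at 0.986 to 0.995. In both genotypes, 684 genes differed by more than 2-fold in the same direction between replicate 1 and the mean of replicates 2 and 3 at 21 °C, 335 higher and 349 lower. Among them GI (AT1G22770), a component of the circadian clock, stood at 9.76 in Col-0 and 9.71 in er-105 in replicate 1 and between 5.51 and 6.38 on the other 4 control arrays. HYH (AT3G17609), a light-signalling transcription factor, stood at 3.97 and 3.75 in replicate 1 and between 7.95 and 8.88 on the others. On the 6 arrays after 40 °C GI stood between 8.54 and 8.97 and HYH between 3.89 and 4.21, on the side of replicate 1. COR15B (AT2G42530), a cold-regulated gene, stood on the side of replicates 2 and 3. For genes such as GI and HYH the heat change cannot be told apart from what separates the control replicates. The 25S rRNA control probe set averaged 8.82 on the 6 arrays at 21 °C and 11.87 on the 6 after 40 °C (exact permutation test, two-sided, p = 0.00216, the smallest that 6 against 6 arrays can give), while the 5′ minus 3′ signal of control transcripts averaged −0.73 and −0.87 (exact p = 0.485).

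**Figure D1:**
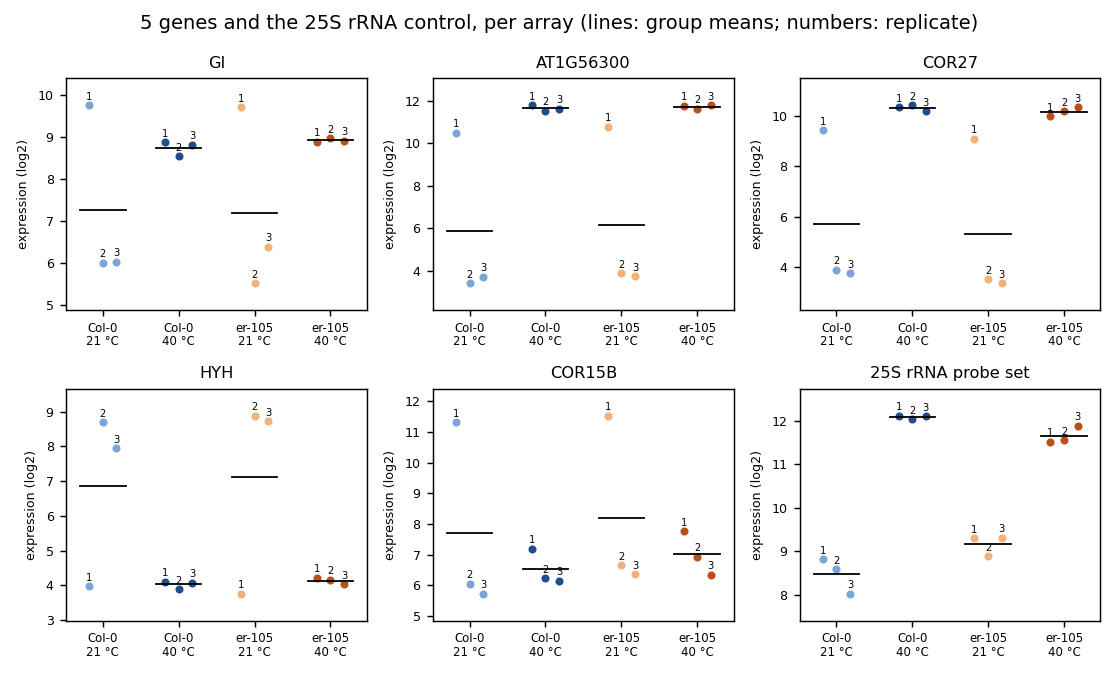
Log2 intensity on each of the 12 arrays, by group, of 5 genes that differed between replicate 1 and the other control arrays and of the 25S rRNA control; numbers are replicates and lines are group means. At 21 °C the replicate 1 arrays of GI stood at 9.76 and 9.71 against 5.51 to 6.38 for replicates 2 and 3, and the 25S rRNA means rose from 8.82 at 21 °C to 11.87 after 40 °C.

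Heat in the wild type raised transcripts of small heat shock proteins and of co-chaperones, and lowered those of a thaumatin-like protein, an expansin and an endoglucanase. HSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, rose from a dim 3.78 ± 0.22 at 21 °C to 12.99 ± 0.17 after 40 °C (SD, n = 3 arrays each, adjusted p = 1.30e-11). The small heat shock protein genes HSP17.6C (AT1G53540) and HSP17.6B-CI (AT2G29500) rose by log2 9.11 ± 0.33 and 8.63 ± 0.22 (SE, n = 3 per group, adjusted p = 2.49e-08 and 2.10e-09). Their means at 21 °C were also dim, at 4.14 and 4.34, so the size of the rise is less certain. The strongest declines were in AT5G48490, which fell by 5.89 ± 0.61 (adjusted p = 3.11e-05), and in ATLP-1 (AT1G18250), a thaumatin-like protein, which fell by 5.05 ± 0.25 (adjusted p = 2.01e-07). EXPA8 (AT2G40610), an expansin that loosens cell walls, fell by 4.47 ± 0.34 (adjusted p = 4.04e-06), and GH9B8 (AT2G32990), of the endoglucanase family, fell by 4.52 ± 0.36 (adjusted p = 5.10e-06). AT4G29030 and AT1G29660 fell by 4.65 ± 0.36 and 4.45 ± 0.61 (adjusted p = 4.62e-06 and 2.12e-04).

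In all, 2170 genes rose and 2176 fell in Col-0, which is 32.5% of the genes tested, and 1059 and 1166 of them changed by at least 2-fold. The 3 heated and 3 control arrays did not overlap for 5834 genes or 43.7%, where chance gives 10%. Scaling the arrays by their median moved the median of all heat changes in Col-0 by 0.17 and the calls to 3430 higher and 1691 lower. Scaling by the hybridization controls moved it by −0.24 and the calls to 1284 higher and 2946 lower. All 20 called genes named by the rule kept their call and direction in Col-0 under every alternative run. They were picked for large changes on these arrays and do not stand for all calls. Of the 4346 calls, 271 were lost without both replicate 1 arrays at 21 °C. Against replicate 1 at 21 °C alone, 468 of the 2225 genes with a change of at least 2-fold (21.0%) differed by less than 2-fold. AT5G48490 then stood at −4.59, AT1G29660 at −3.19 and HSP22.0 at 9.25.

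All 8 measured small heat shock proteins rose in Col-0, over all genes and adjusted over the list alone, with a median of 6.02 (adjusted p for the list = 1.33e-12, and adjusted p = 0.00342 with an estimated correlation). The others were HSP23.5 (AT5G51440, 6.25 ± 0.30), HSP15.7 (AT5G37670, 5.79 ± 0.21), HSP26.5 (AT1G52560, 5.60 ± 0.12), HSP17.4-CIII (AT1G54050, 4.37 ± 0.23) and HSP15.4 (AT4G21870, 2.16 ± 0.17). Of the 6 measured larger chaperones and co-chaperones, 4 rose and 1 fell, and the counts adjusted over the list alone were the same 4 and 1. These were the peptidyl-prolyl isomerase gene ROF2 (AT5G48570), which rose by 6.39 ± 0.34 or 83.6-fold, and HOP3 (AT4G12400), HOP1 (AT1G12270) and HOP2 (AT1G62740), organizers of HSP70 with HSP90, which rose by 6.21 ± 0.32, 1.22 ± 0.17 and 1.21 ± 0.24. HSC70-2 (AT5G02490) fell by 0.87 ± 0.25 (adjusted p = 0.0221), and HSC70-3 (AT3G09440) stood at −0.73 ± 0.40 (adjusted p = 0.202). The list of these chaperones was called at a median of 1.22 with adjusted p = 0.0465, and its adjusted p = 0.717 with an estimated correlation. Without Col-0 21 °C replicate 1 the adjusted p was 0.0981 and without Col-0 40 °C replicate 3 it was 0.0641. It was 0.0642 with the replicate block and 0.195 without both replicate 1 arrays at 21 °C, within a range of camera over the alternatives of 0.00324 to 0.717. On replicate 1 at 21 °C the median of this list stood at −0.98 against the other control arrays.

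Heat also raised genes of protein folding in the endoplasmic reticulum and of autophagy in Col-0. All 5 measured genes of folding and the unfolded protein response rose (5 adjusted over the list alone), with a median of 1.84, and the list was called with adjusted p = 5.60e-04 (adjusted p = 0.0482 with an estimated correlation). Among them BZIP28 (AT3G10800), a membrane-bound transcription factor of the unfolded protein response, rose by 2.00 ± 0.18, DER1 (AT4G29330), of protein degradation, by 1.93 ± 0.20, ERDJ3B (AT3G62600), a DnaJ co-chaperone, by 1.84 ± 0.19 and BZIP60 (AT1G42990) by 0.70 ± 0.18. Of 8 measured ATG8 genes, whose ubiquitin-like products coat autophagosomes, 7 rose (7 adjusted over the list alone), with a median of 1.72. The list was called with adjusted p = 1.25e-04 and lost with an estimated correlation (adjusted p = 0.285). ATG8B (AT4G04620) rose by 2.43 ± 0.20, ATG8H (AT3G06420) by 2.34 ± 0.23 and ATG8A (AT4G21980) by 2.33 ± 0.19, while ATG8G (AT3G60640) stood at −0.15 ± 0.14 (adjusted p = 0.494).

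Transcripts of the organelle genomes moved apart in Col-0, in lists added after the annotation was seen. Of 16 mitochondrion-encoded genes 15 rose, with a median of 3.53 (adjusted p = 9.63e-15, and adjusted p = 0.0482 with an estimated correlation). The complex I subunits nad6 and nad5 rose by 7.38 ± 0.15 and 6.94 ± 0.20 from dim means of 3.63 and 4.04 at 21 °C. Transcripts of cox2 rose by 5.80 ± 0.24 and of cox1 by 5.30 ± 0.26, while nad2 stood at 0.06 ± 0.24 (adjusted p = 0.897). The nuclear genome carries near-identical copies of mitochondrial sequence, so the compartment of origin of these transcripts is uncertain. On the same arrays the 25S rRNA control rose from 8.47 ± 0.41 to 12.1 ± 0.05 (SD, n = 3). Of 69 plastid-encoded genes 27 fell and 4 rose, with a median of −0.35 (adjusted p = 1.15e-04, and adjusted p = 0.717 with an estimated correlation). The plastid ribosomal proteins, which are part of these 69 genes, had 8 of 15 members lower at a median of −0.98 (adjusted p = 1.00e-04, and adjusted p = 0.285 with an estimated correlation), among them rpl16 (−2.85 ± 0.41), rpl22 (−2.61 ± 0.29) and rps19 (−2.53 ± 0.23). In contrast, psbA, of photosystem II, rose by 0.86 ± 0.24.

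Several nuclear families, again in added lists, were called lower in Col-0. Of 10 alpha expansins 3 fell, EXPA8, EXPA4 (AT2G39700, −3.90 ± 0.31) and EXPA15 (AT2G03090, −2.34 ± 0.23), and the list was called at a median of −0.30 (adjusted p = 0.0139, and adjusted p = 0.285 with an estimated correlation). Of 22 trichome birefringence-like genes, a family that acetylates wall polysaccharides, 9 fell at a median of −0.43 (adjusted p = 4.81e-04, and adjusted p = 0.137 with an estimated correlation), with TBL45 (AT2G30010) at −3.20 ± 0.18 and TBL36 (AT3G54260) at −2.28 ± 0.43. Of 15 IQ-domain genes, which encode calmodulin-binding proteins, 8 fell at a median of −0.83 (adjusted p = 9.70e-04, and adjusted p = 0.137 with an estimated correlation), with IQD30 (AT1G18840) at −2.60 ± 0.26 and IQD31 (AT1G74690) at −2.55 ± 0.30. Of 29 serine carboxypeptidase-like genes 8 fell, with SCPL27 (AT3G07990) at −2.18 ± 0.15, and the median of −0.12 became 0.05 with arrays scaled by their median. That list was called with adjusted p = 0.00645 and lost with an estimated correlation (adjusted p = 0.194).

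Among the remaining lists fixed in advance, none was called in Col-0. Of 6 measured photosystem and light-harvesting genes 1 fell (1 adjusted over the list alone), PSAN (AT5G64040, −0.97 ± 0.10), and the list had adjusted p = 0.631. Of 4 Calvin cycle and photorespiration genes 1 fell (1 adjusted over the list alone), SBPASE (AT3G55800, −1.39 ± 0.32, adjusted p = 0.00596), and the list had adjusted p = 0.230. RCA (AT2G39730), the activase of rubisco, stood at −0.05 ± 0.15 (adjusted p = 0.841). In the ERECTA pathway with stomatal development, FAMA (AT3G24140), a transcription factor of guard cell formation, fell by 0.58 ± 0.18 (adjusted p = 0.0266) and the other 4 measured genes did not pass the threshold. That list had adjusted p = 0.770, with a median of 0.08, a mean of −0.07 and a test direction of lower. Of 8 reference genes TIP41-like (AT4G34270, 0.66 ± 0.10) and RHIP1 (AT4G26410, 0.79 ± 0.11) rose and SAND (AT2G28390) fell by 0.49 ± 0.12, and their list had adjusted p = 0.939, with a median of −0.04, a mean of 0.01 and a test direction of higher. With the estimated correlation 3 of the 11 called lists remained, and fry called 18 of 33 lists.

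**Figure D2:**
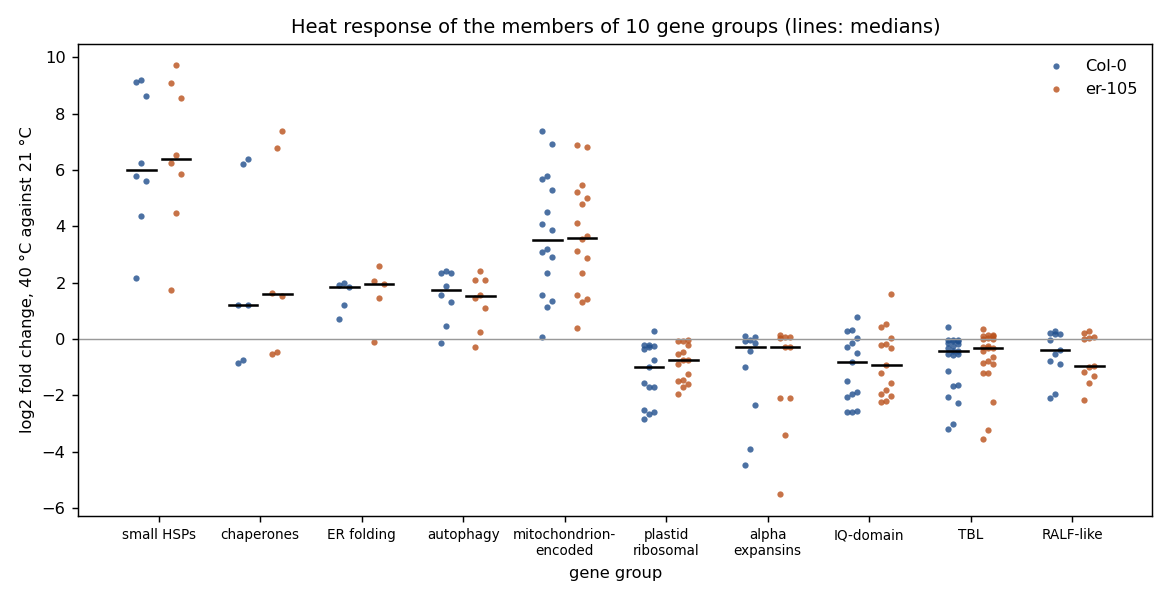
Log2 heat change of each measured member of 10 gene groups, after 40 °C against 21 °C, in Col-0 (blue) and er-105 (orange); points are genes and lines are medians. The medians of small heat shock proteins stood at 6.02 and 6.38 and those of mitochondrion-encoded genes at 3.53 and 3.6, and the alpha expansins stood at −0.30 and −0.27 with EXPA8 at −4.47 and −5.51.

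The same heat treatment of er-105 raised and lowered many of the genes that changed in the wild type. HSP17.6C rose by log2 9.71 ± 0.33 (SE, n = 3 per group, adjusted p = 1.73e-08), HSP22.0 by 9.10 ± 0.13 (adjusted p = 1.49e-11), HSP17.6B-CI by 8.57 ± 0.22 (adjusted p = 2.25e-09) and ROF2 by 7.39 ± 0.34 (adjusted p = 1.49e-07). AT5G48490 fell by 6.00 ± 0.61 (adjusted p = 2.76e-05), EXPA8 fell by 5.51 ± 0.34 or 45.5-fold (adjusted p = 8.97e-07) and AT1G29660 fell by 5.46 ± 0.61 (adjusted p = 5.12e-05). AT3G44450 fell by 4.58 ± 0.35 (adjusted p = 4.20e-06), AT1G73600 fell by 4.40 ± 0.19 (adjusted p = 9.83e-08) and AT1G13650 fell by 4.56 ± 1.07 (adjusted p = 0.00665). AT1G13650 stood at 6.67 on the replicate 1 array of er-105 at 21 °C, and its heat change against that array alone was −2.05.

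In er-105, 2351 genes rose and 2187 fell, which is 34.0% of those tested, and 1107 and 1169 changed by at least 2-fold. The heated and control arrays did not overlap for 6333 genes or 47.4%, against 10% by chance. Scaling by array medians moved the median of all changes by 0.13 and the calls to 3170 higher and 1783 lower. Scaling by the hybridization controls moved it by −0.10 and the calls to 1653 higher and 2204 lower. All 20 called genes named by the rule, again picked for large changes on these arrays, kept their call and direction under every alternative run. Of all 4538 calls, 304 were lost without both replicate 1 arrays at 21 °C. Against replicate 1 at 21 °C alone, 436 of the 2276 genes with a change of at least 2-fold (19.2%) differed by less than 2-fold.

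Chaperone and folding genes rose in er-105. All 8 small heat shock proteins did (8 adjusted over the list alone), at a median of 6.38 (adjusted p = 3.59e-12, and adjusted p = 0.00388 with an estimated correlation). Of the larger chaperones and co-chaperones 4 of 6 rose (4 adjusted over the list alone) at a median of 1.59, with HOP3 at 6.78 ± 0.32 and HOP1 at 1.65 ± 0.17, and the list was called with adjusted p = 0.0172 and lost with an estimated correlation (adjusted p = 0.582) and without both replicate 1 arrays at 21 °C (0.0595), within a range of 0.00217 to 0.582. In endoplasmic reticulum folding 4 of 5 genes rose (4 adjusted over the list alone) at a median of 1.95 (adjusted p = 0.00544, and adjusted p = 0.109 with an estimated correlation), with BZIP28 at 2.59 ± 0.18, ERDJ3B at 2.06 ± 0.19 and DER1 at 1.95 ± 0.20. BZIP60 stood at −0.12 ± 0.18 (adjusted p = 0.681), and its response was not shown to differ from that in Col-0 (interaction −0.81 ± 0.25, adjusted p = 0.999). Of 8 ATG8 genes 6 rose (6 adjusted over the list alone) at a median of 1.51 (adjusted p = 0.00125, and adjusted p = 0.381 with an estimated correlation), with ATG8H at 2.43 ± 0.23, ATG8A at 2.11 ± 0.19 and ATG8B at 2.09 ± 0.20.

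Lists of organelle transcripts and of some nuclear families, all added after the annotation was seen, were also called in er-105. The xyloglucan endotransglucosylases, a further wall family, were not (camera, adjusted p for the list = 0.283). Of 16 mitochondrion-encoded genes 15 rose at a median of 3.6, with nad6 at 6.88 ± 0.15 and nad5 at 6.83 ± 0.20 (adjusted p for the list = 1.06e-14, and adjusted p = 0.0696 with an estimated correlation), and the 25S rRNA control rose from 9.16 ± 0.25 to 11.7 ± 0.20 (SD, n = 3). Plastid-encoded genes had 20 of 69 lower and 2 higher at a median of −0.29 (adjusted p = 0.00125, and adjusted p = 0.671 with an estimated correlation), and plastid ribosomal proteins had 8 of 15 lower at −0.75 (adjusted p = 6.90e-04, and adjusted p = 0.381 with an estimated correlation). Of 10 plastid NAD(P)H dehydrogenase subunits 4 fell, with ndhA at −1.65 ± 0.18, and the list was called at a median of −0.28 (adjusted p = 0.0445, and adjusted p = 0.582 with an estimated correlation). The ribosomal and dehydrogenase lists are parts of the plastid-encoded list, so their calls are not separate results. Trichome birefringence-like genes had 7 of 22 lower at −0.32 (adjusted p = 0.0103, and adjusted p = 0.309 with an estimated correlation), alpha expansins 4 of 10 at −0.27 (adjusted p = 0.0301, and adjusted p = 0.381 with an estimated correlation), and IQ-domain genes 8 of 15 lower and 2 higher at −0.93 (adjusted p = 0.00747, and adjusted p = 0.284 with an estimated correlation). Of 11 RALF-like genes, which encode secreted signalling peptides, 6 fell at a median of −0.94, among them RALFL24 (AT3G23805, −2.16 ± 0.29) and RALFL32 (AT4G14010, −1.56 ± 0.32), and the list was called with adjusted p = 0.0472 (adjusted p = 0.284 with an estimated correlation). The dehydrogenase list was lost without er-105 40 °C replicate 2 (adjusted p = 0.0633) and without er-105 21 °C replicate 1, 2 or 3 (0.0509, 0.0521 and 0.0502). The expansin list was lost without er-105 21 °C replicate 1 (0.0509), and the RALF-like list without er-105 40 °C replicate 3 (0.0544) or 21 °C replicate 3 (0.0983). Without both replicate 1 arrays at 21 °C the dehydrogenase list (0.0577) and the expansin list (0.0595) were lost too. Over the alternatives the adjusted p of camera ranged from 0.0266 to 0.582 for the dehydrogenases, from 0.00965 to 0.381 for the expansins and from 0.0269 to 0.284 for the RALF-like genes.

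The other lists fixed in advance were not called in er-105. PSAN alone fell among the 6 photosystem genes (1 adjusted over the list alone, −1.25 ± 0.10, list adjusted p = 0.218) and SBPASE alone among the 4 Calvin cycle genes (1 adjusted over the list alone, −1.52 ± 0.32, list adjusted p = 0.218), while RCA stood at −0.03 ± 0.15 (adjusted p = 0.921). FAMA fell by 0.74 ± 0.18 in the ERECTA pathway list, whose adjusted p was 0.929 at a median of 0.12, a mean of 1.34e-04 and a test direction of lower. Reference genes had 2 higher and 2 lower (adjusted p = 0.952). With the estimated correlation 1 of the 12 called lists remained, and fry called 15 of 33 lists.

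The heat responses of the genotypes were close across genes. The log2 changes in er-105 and Col-0 correlated at Pearson's r = 0.948 and Spearman's rho = 0.865 over 13355 genes, which are not independent replicates, with a slope of 0.951. Both genotypes shared 1804 genes that rose and 1775 that fell, where independent calls would share 382 and 356, and 2 genes were called in opposite directions. The replicate 1 control arrays of both genotypes deviated alike (r = 0.84), which enters both responses and can add to the agreement. Without both of these arrays Pearson's r was 0.941. Any other difference common to the controls of both genotypes also counts as agreement here. In Col-0 alone 765 genes passed the threshold and in er-105 alone 957, but the difference between the responses itself passed for 3 genes. Of the 4346 genes called in Col-0, 99.1% had a change of the same sign in er-105, whether or not it passed the threshold, and 3579 were called there in the same direction.

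**Figure D3:**
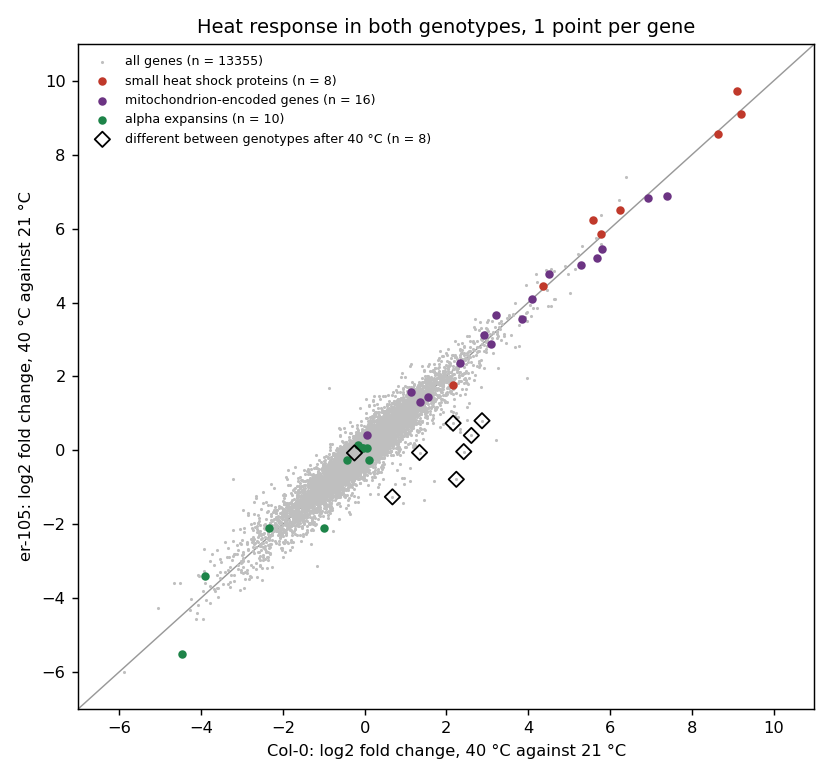
Log2 heat change in Col-0 (horizontal axis) against er-105 (vertical axis) for 13355 genes, with 8 small heat shock proteins in red, 16 mitochondrion-encoded genes in purple, 10 alpha expansins in green and the 8 genes that differed between genotypes after 40 °C as open diamonds. Pearson's r across genes was 0.948, and AT2G25735 stood at 2.42 in Col-0 and −0.04 in er-105.

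At 21 °C no named gene separated er-105 from the wild type past the threshold in the model without a block. HSP17.6C differed by −0.58 ± 0.33 and RCA by −0.01 ± 0.15 (SE, n = 3 per group, adjusted p = 1.00 for both). Of the 5 measured genes of the ERECTA pathway list, FAMA stood at 0.61 ± 0.18, EPFL9 (AT4G12970), the peptide stomagen that promotes stomata, at 0.36 ± 0.23, SPCH (AT5G53210), which starts the stomatal lineage, at 0.24 ± 0.17, MUTE (AT3G06120) at 0.00 ± 0.13 and EPFL1 (AT5G10310) at −0.16 ± 0.24, none of them past the threshold over all genes. With limma, 0 genes were higher and 0 lower, without moderation 0 passed as well, and 520 genes had an unadjusted p under 0.05, where 668 would by chance. The arrays did not overlap for 1036 genes or 7.76%, against 10% by chance. Both chance values hold for unpaired arrays, and an effect shared by pairs of arrays lowers both counts, so they show no lack of difference. The replicate block also gave 0 genes. A block within each temperature, tried after the data had been seen, gave 5 higher and 5 lower. Without Col-0 21 °C replicate 1, 3 genes were higher and 4 lower, without er-105 21 °C replicate 1, 0 and 2, and without both, 25 and 25.

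Small shifts of whole lists were called at 21 °C with 0 members past the threshold over all genes in any of them. The ERECTA pathway list was higher in er-105 at a median of 0.24 (adjusted p = 0.0454, and adjusted p = 0.470 with an estimated correlation), and 1 member passed when adjusted over the list alone. Photosystem and light-harvesting genes stood at 0.12 (adjusted p = 0.0208, and adjusted p = 0.470 with an estimated correlation) and ATG8 genes at 0.16 (adjusted p = 0.0208, and adjusted p = 0.728 with an estimated correlation). Among added lists, plastid NAD(P)H dehydrogenase subunits stood at 0.27 (adjusted p = 0.00142, and adjusted p = 0.487 with an estimated correlation). Plastid-encoded genes at 0.09, plastid photosystem subunits at 0.12 and mitochondrion-encoded genes at 0.06 had adjusted p = 0.0208 each, and each had adjusted p = 0.728 with an estimated correlation. The dehydrogenase and plastid photosystem lists are parts of the plastid-encoded list, so their calls are not separate results. Without Col-0 21 °C replicate 3 the medians of plastid-encoded genes and plastid photosystem subunits turned to −0.11 and −0.077. The cytochrome P450 subfamily 71B stood at 0.11 (adjusted p = 0.0461, and adjusted p = 0.728 with an estimated correlation) and serine carboxypeptidase-like genes at −0.12 (adjusted p = 0.0208, and adjusted p = 0.470 with an estimated correlation). All 9 calls were lost without Col-0 21 °C replicate 2 (adjusted p from 0.0571 to 0.252). Without er-105 21 °C replicate 2, 8 were lost (0.0877 to 0.781), without Col-0 21 °C replicate 3, 6 (0.0501 to 0.939), without er-105 21 °C replicate 1, 6 (0.0503 to 0.120), without er-105 21 °C replicate 3, 5 (0.0692 to 0.250) and without Col-0 21 °C replicate 1, 3 (0.175 to 0.190). With a block within each temperature 5 of the 9 were lost (0.0607 to 0.0754), and without both replicate 1 arrays 3 (0.0534 to 0.218). Larger chaperones and co-chaperones stood at −0.21 (adjusted p = 0.0857). They were called lower in er-105 with the replicate block (0.0278), with a block within each temperature (0.0451) and without both replicate 1 arrays (0.00319), within a range over the alternatives of 5.78e-05 to 0.728. Of this list, ROF2 stood at 6.81 on Col-0 21 °C replicate 3, against 5.03 and 5.79 on replicates 1 and 2 and 4.90 to 4.98 in er-105. HOP3 and HOP1 stood close to replicate 2 there (4.95 against 4.73 and 8.10 against 8.07). HSP17.6C, outside the list, stood at 5.16 there, against 3.65 and 3.61. How far these calls rest on that array was not tested. Small heat shock proteins were not called (adjusted p = 0.705), with a median of −0.00 and a test direction of higher.

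After 40 °C, er-105 held less transcript than the wild type of a small set of named genes. WRKY53 (AT4G23810), a transcription factor of senescence and defence, was lower, at a dim 4.1 ± 0.09 in er-105 and 6.66 ± 0.69 in Col-0 (SD, n = 3, adjusted p = 0.0371). AT3G10930 differed by −1.86 ± 0.21, AT2G32190 by −1.78 ± 0.19, AT2G25735 by −1.74 ± 0.21 and AT2G22880 by −1.28 ± 0.15 (SE, n = 3 per group, adjusted p = 0.0160 for each), and AT5G52750 by −1.22 ± 0.16 (adjusted p = 0.0274). AT3G59080, chosen after its value was seen, differed by −1.13 ± 0.16 (adjusted p = 0.0376). A probe set shared by AT2G32190 and AT2G32210, and so outside the 13355 genes, differed by −2.05 ± 0.18 (adjusted p = 0.00314 over all probe sets other than controls). In all, 7 probe sets outside these genes were called after 40 °C, 4 higher and 3 lower in er-105. AT1G33930 was higher in er-105, by 1.29 ± 0.18 (adjusted p = 0.0397), and stood at 1.11 ± 0.18 at 21 °C (adjusted p = 0.296). Its mean in Col-0 after 40 °C was a dim 3.83. In er-105 after 40 °C the means of AT3G10930 and AT2G22880 were dim as well, at 4.21 and 4.15. The size of the differences of these genes and of WRKY53 is thus less certain. The small heat shock protein HSP17.6C differed by 0.02 ± 0.33 and RCA by 0.01 ± 0.15 (adjusted p = 1.00 for both).

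The heat response in Col-0 shares the Col-0 arrays after 40 °C with this difference, so a rise there is in part built into genes picked as lower in er-105. In Col-0, WRKY53 rose by 2.24 ± 0.35, AT3G10930 by 2.61 ± 0.21, AT2G32190 by 2.87 ± 0.19, AT2G25735 by 2.42 ± 0.21, AT3G59080 by 2.16 ± 0.16, AT2G22880 by 1.34 ± 0.15 and AT5G52750 by 0.68 ± 0.16. At 21 °C in Col-0, WRKY53, AT3G10930, AT2G32190, AT2G25735 and AT2G22880 were dim, at 4.42, 3.46, 3.52, 4.39 and 4.085, so the size of their rise is less certain. In er-105, AT2G32190 and AT3G59080 rose by 0.80 ± 0.19 and 0.73 ± 0.16, AT5G52750 fell by 1.26 ± 0.16 (adjusted p = 1.10e-04), and the other 4 did not pass the threshold. The arrays after 40 °C did not overlap for all 8 genes, nor for 1837 of all genes (13.8%), where chance gives 10%. By limma 1 gene was higher and 7 lower, 600 genes had an unadjusted p under 0.05, where 668 would by chance, and 0 passed without moderation. The errors of this contrast come from all 4 groups, so the spread of the control arrays at 21 °C enters them. The count of 600 therefore shows no lack of difference. On its own arrays the contrast gave 13 genes higher and 30 lower. No gene passed when Col-0 40 °C replicate 2 or 3 or er-105 40 °C replicate 1, 2 or 3 was left out, and 1 higher and 4 lower passed without Col-0 40 °C replicate 1. With the replicate block 4 of the 8 were called, and adjusted p rose to 0.0876 for WRKY53 (range over the alternatives 0.00105 to 0.214), 0.0658 for AT2G25735 (1.46e-04 to 0.166) and 0.0876 for AT5G52750 (0.00141 to 0.214), and AT3G59080 was lost at 0.100. Without both replicate 1 arrays at 21 °C, 19 genes were higher and 37 lower, all 8 among them.

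**Figure D4:**
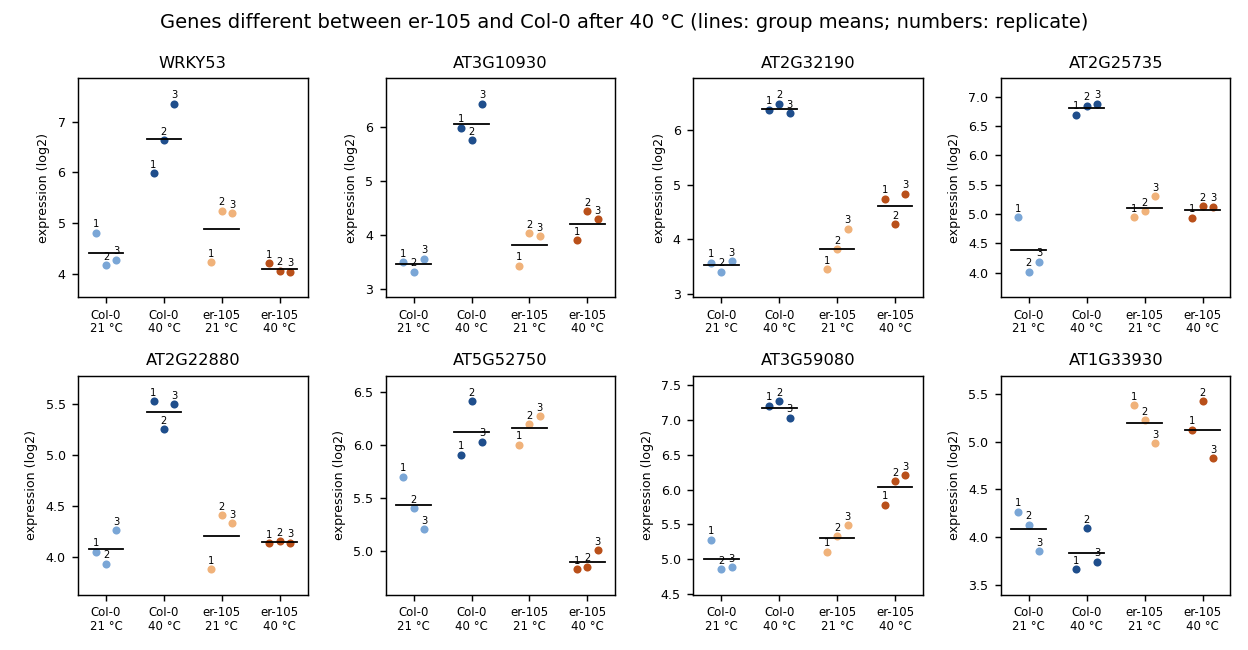
Log2 intensity on each of the 12 arrays, by group, of the 8 genes that differed between er-105 and Col-0 after 40 °C; numbers are replicates and lines are group means. WRKY53 averaged 6.66 in Col-0 and 4.1 in er-105 after 40 °C, and AT1G33930 was higher in er-105 by 1.29.

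Lists after 40 °C again shifted with 0 members past the threshold. The ERECTA pathway list was higher in er-105 at a median of 0.30, with SPCH at 0.46 ± 0.17, FAMA at 0.45 ± 0.18 and EPFL9 at 0.30 ± 0.23 (adjusted p = 0.0398, and adjusted p = 0.408 with an estimated correlation), and 0 members passed when adjusted over the list alone. Plastid-encoded genes stood at 0.25 (adjusted p = 2.29e-07, and adjusted p = 0.693 with an estimated correlation). Plastid photosystem subunits at 0.20 and plastid ribosomal proteins at 0.26 had adjusted p = 0.0398 each, and adjusted p = 0.693 with an estimated correlation. Both lists are parts of the plastid-encoded list, so their calls are not separate results. RALF-like genes stood at −0.19 (adjusted p = 0.0410, and adjusted p = 0.408 with an estimated correlation). They were lost with the replicate block (0.0605) and with a block within each temperature (0.0895), within a range of 0.0136 to 0.408. In none of the 3 genotype contrasts did fry call any of the 33 lists. The list of plastid-encoded genes kept its call when any 1 of the 6 arrays after 40 °C was left out. Of the other 4 lists, 3 were lost without Col-0 40 °C replicate 1 (adjusted p from 0.0914 to 0.0993), 3 without Col-0 40 °C replicate 2 (0.0843 to 0.173), 2 without Col-0 40 °C replicate 3 (0.153 to 0.326), 4 without er-105 40 °C replicate 1 (0.0960 to 0.104), 1 without er-105 40 °C replicate 2 (0.0569) and 3 without er-105 40 °C replicate 3 (0.0971 to 0.152).

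The heat response itself differed between the genotypes for 3 genes, each with a lower change in er-105 than in Col-0. The interaction was −2.46 ± 0.29 for AT2G25735 (adjusted p = 0.0326), −2.07 ± 0.27 for AT2G32190 (adjusted p = 0.0477) and −1.94 ± 0.22 for AT5G52750 (adjusted p = 0.0326; SE, n = 3 per group). For WRKY53 it was −3.03 ± 0.49 (adjusted p = 0.132), for AT3G10930 −2.21 ± 0.30 (adjusted p = 0.0609), for AT2G22880 −1.40 ± 0.21 (adjusted p = 0.0942) and for AT3G59080 −1.43 ± 0.22 (adjusted p = 0.117). HSP17.6C and RCA had interactions of 0.60 ± 0.47 and 0.03 ± 0.21 (adjusted p = 0.999 for both). The serine carboxypeptidase-like genes were the 1 list called on all 12 arrays without a block, at a median of 0.14 (adjusted p = 0.0363, and adjusted p = 0.477 with an estimated correlation) with 0 members past the threshold. Larger chaperones and co-chaperones stood at 0.42 (adjusted p = 0.102). They were called higher with the replicate block (0.0117), with a block within each temperature (0.0111) and without both replicate 1 arrays at 21 °C (7.27e-04), within a range of 6.78e-05 to 0.826. The high ROF2 value on Col-0 21 °C replicate 3 enters these calls as well. Plant U-box ubiquitin ligases stood at −0.40 (adjusted p = 0.132). They were called lower with a block within each temperature (0.0167) and without both replicate 1 arrays (7.27e-04), within a range of 7.27e-04 to 0.477. Both upper ends are those of the estimated correlation. A block within each temperature called 2 further lists and omission of both replicate 1 arrays 2 others. Among these, the plastid-encoded genes turned from a median of 0.16 on all 12 arrays to −0.08 without both replicate 1 arrays.

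By limma 0 genes had a higher interaction and 3 a lower one, 566 had an unadjusted p under 0.05, where 668 would by chance, and 0 passed without moderation. That chance value holds for unpaired arrays, and an effect shared by arrays at 21 °C lowers the count here too, so it shows no lack of difference. With the replicate block 0 passed, and with a block within each temperature, tried after the data had been seen, 2 were higher and 7 lower, the 3 genes among them. The count of lower genes was 0 without Col-0 40 °C replicate 2 or 3, Col-0 21 °C replicate 2 or 3, er-105 40 °C replicate 1, 2 or 3, or er-105 21 °C replicate 2 or 3. Without er-105 21 °C replicate 1, 15 were lower and 1 higher, and without both replicate 1 arrays at 21 °C 34 and 8, the 3 genes among them. With replicate 1 as the only controls 1 was lower and none of the 3 passed: AT2G25735 stood at −1.74, AT2G32190 at −1.65 and AT5G52750 at −1.52 (adjusted p = 0.0766, 0.197 and 0.212). Over the alternatives their adjusted p ranged from 1.15e-04, 0.00276 and 0.00191 to 0.296 each. The carboxypeptidase list was lost without Col-0 40 °C replicate 2 (adjusted p = 0.134) or 3 (0.104), Col-0 21 °C replicate 1 (0.130), er-105 40 °C replicate 2 (0.109), and er-105 21 °C replicate 2 (0.0643) or 3 (0.0998), within a range over the alternatives of 0.00267 to 0.477.

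The er-105 allele lies on chromosome 2, and the order of loci was used to ask whether genes that differed after 40 °C lay near it. Of the 8 genes 2 lay within 500 loci of the ERECTA locus, AT2G25735 and AT2G22880, against 366 of 13355 genes or 2.74% (Fisher's exact test, two-sided, p = 0.0188). Within 1000 loci there were 3, AT2G32190 as well (p = 0.00746 by the same exact test), and within 250 loci 1, AT2G25735 (exact p = 0.104). The exact test takes genes as independent, but 7 of the 8 moved together, higher with heat in Col-0 and lower in er-105 after 40 °C. These p-values can therefore be too small, and linkage to ERECTA was not shown.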

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

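The test on plastid-encoded transcripts, the splits that part the pairs, the lists of organelle-encoded genes and the fits without both replicate 1 arrays at 21 °C, with a block within each temperature or with the 5′ minus 3′ covariate were chosen only after the results were seen. Single deviating arrays within the groups of 3 were not tested.

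The heat response differed between er-105 and Col-0 by a test of the difference itself for AT2G25735 (−2.46), AT2G32190 (−2.07) and AT5G52750 (−1.94), which also belong to the 7 genes lower in er-105 after 40 °C. Over 4 other scalings the highest median of those 7 genes after 40 °C was −1.65, against a bound of −1 set beforehand. These scalings moved the median of all genes by only −0.01 to 0.09, too little to undo differences of that size. The test thus shows that none of the 4 accounts for the difference, and it could not decide on scaling in general. The 3 interaction calls ended with hybridization controls at −2.32, −1.93 and −1.80 (adjusted p = 0.123, 0.123 and 0.145) and that of AT2G32190 with reference genes at −2.04 (0.185), within ranges whose upper end was 0.296 for each. Handling at harvest, such as touch or wounding, may have differed between the genotypes and cannot be told apart from the mutation: 10 other fast-responding genes had a median difference of −0.44, between the bounds of −0.5 and −0.25 set beforehand, and all 10 were lower in er-105 with 0 past the threshold. The mutation itself stays open as well and was not tested apart from handling.

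Of 100 drawn splits that moved the genotype labels within each temperature, the real one included, 3 gave at least the 3 genes of the real interaction, and the highest other count was 9, so the share of splits was under 0.05. Among all 80 splits that part the 3 pairs of equal replicate numbers at 21 °C, as the real one does, 3 also gave at least 3 genes and the highest other gave 9, while with the replicate block the real split gave 0 genes and the highest other 10. For the difference after 40 °C, 1 of the 10 splits of the 6 arrays, the real one, gave as many as its 8 genes and the highest other gave 0, but 10 splits are too few for a share under 0.05.

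The 25S rRNA control probe set, which belongs to no gene compared, was higher by 3.05 after 40 °C than at 21 °C, on arrays where 15 of 16 mitochondrion-encoded genes also rose. A higher share of RNA without a poly(A) tail in all compartments was tested on plastid-encoded genes, whose median heat change it was taken to put above 1. The medians were −0.35 in Col-0 and −0.29 in er-105. That bound was written after the results were seen, and a fall in plastid RNA itself could hide such a rise. The test therefore cannot decide on this explanation. Over 4 other scalings and both genotypes the lowest median of the mitochondrion-encoded genes was 3.29. These scalings moved the median of all heat changes by only −0.24 to 0.17, too little to undo a rise of that size. None of the 4 thus accounts for the rise, and the test could not decide on scaling in general. What also stays open and was not tested is a change in mitochondrial RNA itself, in its polyadenylation, or in transcripts of near-identical nuclear copies, so the rise may have more than 1 source.

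Probe sets with no gene or with several genes listed were outside the comparisons, and 5 of these 9233, all with no gene, differed between the genotypes at 21 °C. After 40 °C 7 of the 9233 differed, 4 higher and 3 lower in er-105. Among them 247599_at stood at 1.60, 256671_at at 1.12 and 253414_at at −0.94 (adjusted p = 0.0220, 0.0330 and 0.0414 over all probe sets other than controls). Probe set 267376_at differed by −4.86 between er-105 and Col-0 at 21 °C, with means of 4.47 and 9.33 (adjusted p = 2.04e-04 over all probe sets other than controls), and differed by −3.01 after 40 °C (adjusted p = 0.00594). Probe set 262040_at was higher in er-105 by 1.90 at 21 °C (adjusted p = 0.00341) and by 1.68 after 40 °C. Probe set 262543_at was higher in er-105 by 1.88 at 21 °C (adjusted p = 0.0220) and by 2.69 after 40 °C. Probe set 266415_at differed by −1.31 at 21 °C (adjusted p = 0.0215) and by −0.11 after 40 °C (adjusted p = 1.00). Probe set 262704_at differed by −0.91 at 21 °C (adjusted p = 0.00501) and by −0.12 after 40 °C (adjusted p = 1.00). On all 12 arrays 267376_at, 262040_at and 262543_at did not overlap between the genotypes, as sets picked for a difference on these arrays.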

How the results depend on the processing

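The fits without both replicate 1 arrays at 21 °C, with these as the only controls, with the 5′ minus 3′ covariate and with a block within each temperature were chosen after the data had been seen, as were the added lists. The log2 of value + 16 was not run because the values are already log2, and separate ERECTA probe sets were not run because none carries that name in the list used. With each contrast on its own arrays there is no interaction. Of the called genes named by the rule, which were picked for large changes on these arrays, all 20 of each heat response kept their call under every alternative. Each of the 7 for the genotype difference after 40 °C and of the 3 for the interaction lost it under at least 1. Of the lists, 3 of 11 kept their call under every alternative in Col-0 heat, 1 of 12 in er-105 heat and 0 of the 9, 5 and 1 of the genotype contrasts. The estimated correlation ended 34 list calls and fry 16. The replicate block changed the calls of 4 genes after 40 °C, of 3 for the interaction and of 4 list tests, and no other call of a list or of a gene named by the rule. Where no reason is given, the cause was not tested.

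For heat in Col-0, genes higher numbered 3430 with array medians and 1284 with hybridization controls. All probe sets gave 3819 higher and 4222 lower in Col-0 and 4121 and 4173 in er-105, since more features were counted, and a change of at least 2-fold gave 1059, 1166, 1107 and 1169, since the threshold was stricter. The correlation of the responses was 0.963 among genes called in either genotype. Within 250 loci of ERECTA lay 1 of the 8 genes, and the exact p of 0.104 no longer passed 0.05.

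For the genotype difference at 21 °C, with 0 genes called, all probe sets gave 2 higher and 4 lower, omission of both replicate 1 arrays 25 and 25, and the block within temperature 5 and 5. Array weights gave 3 lower, and 1 lower came each from trend and robust moderation, array medians, quantile normalization and omission of dim genes.

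For the difference after 40 °C, with 1 higher and 7 lower, the counts were 13 and 30 on its own arrays, 6 and 12 with trend and robust moderation, 11 and 22 with array weights, 19 and 37 without both replicate 1 arrays, 25 and 23 with the block within temperature, and 0 and 0 with no moderation or at an adjusted p under 0.01. Hybridization controls gave 0 and 4. Genes higher alone moved to 4 with array medians, quantile normalization or dim genes left out, 3 with reference genes, 5 with all probe sets and 2 with the covariate. Genes lower alone moved to 3 with the replicate block.

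For the interaction, with 3 genes lower, the count was 11 with array weights, 34 (8 higher) without both replicate 1 arrays, 7 (2 higher) with the block within temperature, 1 with replicate 1 as the only controls, and 0 with no moderation, the replicate block, hybridization controls or an adjusted p under 0.01.

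With 1 array left out at a time, counts of genes higher and lower ranged from 1832 to 2208 and 1825 to 2245 for heat in Col-0, from 1892 to 2312 and 1752 to 2154 for heat in er-105, from 0 to 3 and 0 to 4 at 21 °C, from 0 to 1 and 0 to 4 after 40 °C, and from 0 to 1 and 0 to 15 for the interaction, and the correlation of the heat responses from 0.919 to 0.951. With replicate 1 as the only controls each control group had 1 array, which was assumed to vary like the other groups. List medians turned at 21 °C without Col-0 21 °C replicate 3 for plastid-encoded genes (−0.11, range to 0.26) and for plastid photosystem subunits (−0.077, range to 0.33), both uncalled then. Over all such fits, leaving out 1 array ended 66 list calls besides these 2 and kept 166, and ended 69 calls of named genes and kept 309. Signal near the background limits changes of dim genes, and 8013 of the genes lay above the brightness filter.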

Other observations

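The fits without both replicate 1 arrays at 21 °C, the median of small heat shock proteins on replicate 1, the share of the replicate 1 shift given by 5′ signal and the choice of genes shown per array were tests chosen only after the results were seen, and the slope on 5′ signal was redefined before the test of genes kept was run, after control probe values had been seen.

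With the 4 control arrays of replicates 2 and 3 as the only controls, 25 genes stood higher and 25 lower in er-105 than in Col-0 at 21 °C. Among those higher, ZAT10 (AT1G27730), a zinc finger repressor, differed by 2.39 ± 0.42 (SE, adjusted p = 0.0444) and CML38 (AT1G76650), a calmodulin-like protein, by 1.72 ± 0.27 (adjusted p = 0.0207). AT2G25735 and AT5G52750, which were lower in er-105 after 40 °C, differed by 1.08 ± 0.14 and 0.93 ± 0.17 at 21 °C (adjusted p = 0.0112 and 0.0457). Lower in er-105 were AT2G20870 (−3.29 ± 0.20), AT5G22430 (−3.20 ± 0.19) and ARPN (AT2G02850), a plantacyanin, at −1.63 ± 0.19 (adjusted p = 2.68e-05, 2.68e-05 and 0.00605). On all 12 arrays none of these genes passed the threshold at 21 °C, and ARPN stood at −1.45 (adjusted p = 0.0536).

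Some genes stood far apart between the replicate 1 control arrays and replicates 2 and 3. AT1G56300 stood at 10.50 in Col-0 and 10.79 in er-105 in replicate 1, between 3.43 and 3.90 on the other 4 control arrays and between 11.53 and 11.80 on the heated ones. COR27 (AT5G42900), a cold-regulated gene, stood at 9.42 and 9.08, between 3.35 and 3.89, and between 9.99 and 10.42. COR15B (AT2G42530), also cold-regulated, stood at 11.3 and 11.5 in replicate 1, between 5.7 and 6.6 on the other control arrays and between 6.1 and 7.8 on the heated ones.

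A candidate explanation for the replicate 1 control arrays is a harvest at another time of day, since AT1G69570, a morning-phased gene, differed by −1.27 in Col-0 and −2.11 in er-105, past the −1 set beforehand. That gene turned out to be among the 684 itself, so the result stays a hypothesis, and no harvest time is given in the sources used here. If it holds, the heat contrasts would also contain a part from time of day, which was not tested apart from heat. Heat that reached these plants was argued against, since the small heat shock proteins had median differences of −0.26 and −0.24 where it needs a rise. Lower 5′ signal was argued against as the cause of the whole pattern, since its slope within groups on the other 10 arrays gave a median of 9.05% of the shift of the 684 genes in Col-0 and 2.88% in er-105, with ranges of 1.07% to 11.4% and 0.369% to 3.52% when 1 of these arrays was left out, the low ends without er-105 21 °C replicate 2 or 3, on which the slope largely rests. It stays open for a part of the genes, since after that slope was removed 78.2% still differed by more than 2-fold in both genotypes, just under the 80% set beforehand, and other differences between batches of plants were not tested.

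Splits of the 6 arrays of a contrast into 3 against 3 number 10, too few for a share under 0.05. For heat in Col-0, 1 split, the real one, gave as many as its 4346 genes and the highest other gave 0. For heat in er-105, 1 split, the real one, gave as many as its 4538 genes and the highest other gave 0. For the genotype difference at 21 °C the real split gave 0 genes, which all 10 splits reach by construction, so the count tests nothing there. The highest other gave 198 genes, which points to a structure of these samples. That split parts 1 pair of arrays with equal replicate numbers, and among the splits that part all 3 pairs, as the real one does, the highest other gave 3 genes.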
